A study of Homo sapiens with 6 samples.

How the data were processed

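Gene expression was measured by RNA sequencing in 6 libraries of HMC3, an established human microglial cell line. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented, primed at random and sequenced from both ends of each fragment, and the labels name several instruments without saying which was used for which library. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.7 and aligned with HISAT2 2.2.1, DESeq2 1.40.2 was used, and the genome build was GRCh38. The read counter, the annotation used for counting and the use of strand are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart.

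The authors deposited a table with raw counts per gene, whole numbers that were not normalized, and, per the file headers, a log2 fold change, a p-value and an adjusted p-value from their own comparison. The largest adjusted p-value in the authors' deposited table was 0.05, so its 5117 genes are those that passed the authors' threshold. The relation between p, adjusted p and rank in the table gave the number of genes that had been adjusted over, of which those with a row were 40.7%, and this relation was the same for the smallest and the largest p-values. Genes without a row were not analysed here. The column totals, 12730766 to 14961744 counts, therefore cover part of each library and are not its sequencing depth. Tests on genes that had already been selected by a test on the same libraries give no independent evidence that a gene changed, and serve here to give sizes, errors and alternatives.

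Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filterByExpr function removed 1 gene, RNY1, and 5116 genes were tested with TMM scaling and the quasi-likelihood test, group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 5116 genes and a threshold of 0.05. TMM assumes that most of the genes it uses do not change between libraries, and a table of called genes does not ensure that. Standard errors are the log2 fold change divided by the square root of the test's F value. A fold against libraries at 0 counts is a lower bound, computed against 3 counts in each control library, and covers counting error only. The design, the gene lists, the named-gene rule and the alternatives, unless said to be added later, were fixed before the data were examined.

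The 31 gene lists took in metabolism, immune and stress responses, markers of other cell types and RNA quality, and the 25 with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry (limma 3.58.1). The genes named are C1S and C1R, the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 1 CPM whose groups did not overlap, and the up to 4 members of each list with the smallest p. C1S and C1R have no row, so the planned C1S transcript level is not reported here. The other parts of the rule gave 120 genes, of which 5 are not reported here. Genes named outside the rule were chosen after their values were seen. Counts of list members that rose or fell are of members with a row. The other members did not pass the authors' threshold or were not among the genes adjusted over.

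GENCODE release 29, on GRCh38, held 5113 of the 5117 gene identifiers and gave coordinates, gene types and the GC content and length of a representative transcript per gene. After the data had been seen, offsets per library were added from a loess fit of log2 CPM on GC content and log2 length (span 0.3, 5112 genes tested). The representative transcript (by principal-isoform and support level) replaced the longest after results with the longest had been seen, and both are kept as alternatives. The offsets were fitted on called genes alone, and they would also remove a biological difference that followed GC content.

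The steps were tested on simulated counts for the 5117 genes with 200 changed genes. All other simulated genes were unchanged, and the simulated trend followed GC content alone. The table instead holds called genes, and its fold changes also followed transcript length. The rates below therefore show that the steps run as intended and do not carry over to this table. Without a GC trend the comparison of C1s-CM with control CM recovered 79.1% of genes changed by 0.3 on the log2 scale, 98.5% of those changed by 0.6 and 98.5% of those changed by 1, and 3.2% of its calls were unchanged genes. With a GC trend added, 4113 genes were called, of which 95.7% were unchanged, and the offsets brought this to 187 calls, of which 2.1% were unchanged. Camera found the 1 list that had been moved and called 0 of the others. The simulated genes were drawn independently of each other and the lists at random. This therefore does not test the preset correlation for lists whose genes vary together, where the estimated correlation reached 0.36 (ribosomal proteins).

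The alternatives were size factors of DESeq2 (RLE), total counts only, no filter and a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, and the adjustments and offsets added later. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 2.02 to 4.96), so none was counted as a duplicate.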

Results

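RNA was sequenced from HMC3 cells, a human microglial cell line, after treatment with C1s-CM (3 libraries) or with control CM without C1s (3 libraries, titled FLAG). C1s is a serine protease of the classical complement pathway, and the series title places the comparison in a study of immunosuppression and microglial metabolism in glioblastoma. The table analysed holds the 5117 genes that passed the authors' threshold, and genes without a row were not analysed here. Its counts summed to 14227590, 14961744 and 14195082 in the C1s-CM libraries and to 12730766, 13531335 and 13863120 in the control libraries, which is a part of each library. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

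The largest differences were 5 immune and growth factor genes with 199 to 433 counts in every C1s-CM library and 0 in every control library. CXCR4, the receptor for the chemokine CXCL12, had 433, 411 and 421 counts, or 30.5 ± 1.497 CPM (SD, n = 3), and was at least 142-fold higher. CD163, a haptoglobin-hemoglobin scavenger receptor of macrophages, had 322, 231 and 311 counts and was at least 97.0-fold higher. CD209, a C-type lectin of dendritic cells and macrophages, had 279, 269 and 266 counts and was at least 91.2-fold higher. CCR2, the receptor for the chemokine CCL2, had 213, 223 and 219 counts and was at least 73.3-fold higher. IGF1, which encodes insulin-like growth factor 1, had 211, 199 and 207 counts and was at least 69.1-fold higher. The bounds are set against 3 counts in each control library. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p of the 5 was that of CD163, 4.76e-15. These 5 were the only genes of the table with a count of 0 in any library.

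**Figure D1:**
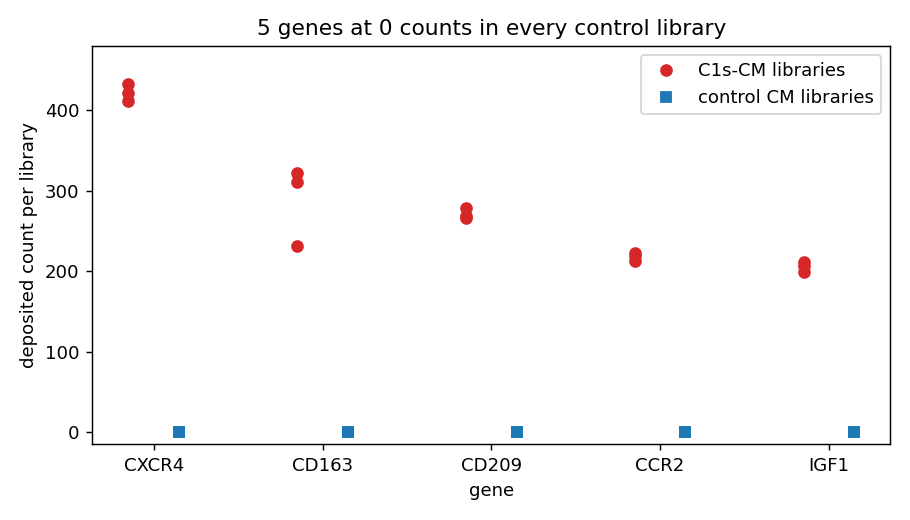
Deposited counts per library (vertical axis) of the 5 genes with no counts in control CM (horizontal axis), with 3 C1s-CM libraries as circles and 3 control CM libraries as squares. The C1s-CM counts lie between 199 and 433, and every control count is 0.

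On GRCh38, CXCR4 lies on the minus strand of chromosome 2 (136114349 to 136118165) and CCR2 on the plus strand of chromosome 3 (46353734 to 46360928). CD163 (7470813 to 7503893) and IGF1 (102395874 to 102481744) lie on the minus strand of chromosome 12, and CD209 on that of chromosome 19 (7739994 to 7747564). All 5 are annotated as protein-coding, and the coordinates span the whole gene.

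Among genes with a mean of at least 1 CPM whose groups did not overlap, the next largest rises were a small RNA, a noncoding RNA and a pseudogene at low levels. BCYRN1, a short cytoplasmic RNA derived from an Alu repeat, rose by 2.96 ± 0.46 on the log2 scale (SE, adjusted p = 3.45e-06), from 0.572 ± 0.134 to 4.53 ± 3.12 CPM (SD, n = 3 per group, edgeR). Its counts were 19, 65 and 104 in C1s-CM, and without C1s-CM replicate 3 the rise of BCYRN1 was 2.37. LINC00337 rose by 1.00 ± 0.24 and UBBP4, a ubiquitin pseudogene, by 0.96 ± 0.23. The noncoding RNA FP236383.5, named after its values were seen, was 1.08 higher with overlapping groups. Repeat copies of BCYRN1 and the ubiquitin genes that resemble UBBP4 make both counts uncertain.

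The 8 largest falls included genes of signalling and nuclear transport. KPNA5, an importin alpha subunit, fell by 1.47 ± 0.22 on the log2 scale (SE), from 4.22 ± 0.420 to 1.52 ± 0.338 CPM (SD, n = 3 per group, adjusted p = 1.66e-06, edgeR). The log2 fold change was -1.15 ± 0.22 for PDE4D, a cyclic AMP phosphodiesterase, -1.14 ± 0.20 for BIRC3, an inhibitor of apoptosis induced by NF-kB, and -1.13 ± 0.16 for the cytokine receptor kinase JAK2. It was -1.12 ± 0.23 for the zinc finger gene ZC3H6 and -1.09 ± 0.28 for the noncoding RNA FTX. The noncoding RNA AC093297.2 had -1.31 ± 0.25, and AC097448.1, which had no match in the annotation, -1.19 ± 0.19. With offsets for transcript GC content and length the log2 change of KPNA5 was -0.76, of PDE4D -0.95, of JAK2 -0.64 and of AC093297.2 -0.79, all still past the threshold. BIRC3 (-0.51), ZC3H6 (-0.57) and FTX (-0.74) then missed it, and AC097448.1 had no GC value.

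Most genes differed little in size. Of 5116 genes tested, 5086 passed adjusted p 0.05 in edgeR, 2605 higher and 2481 lower in C1s-CM, with a median absolute log2 fold change of 0.31. At least 2-fold changes were found for 7 genes that rose and 21 that fell. The authors' deposited table had 2636 genes higher and 2481 lower, and all 5116 tested genes had the same sign in both. The 3 libraries of each group did not overlap for 97.2% of genes, where chance gives 10%, but the table was selected for such genes. Total counts as the only scaling moved the median log2 fold change from 0.08 to -0.05, gave 3853 calls, 1336 higher and 2517 lower (34.7% higher against 51.2%), and 54 genes at least 2-fold lower, whereas the filter of 50 counts left 10. Without C1s-CM replicate 1 or without control CM replicate 2, 11 genes were at least 2-fold higher.

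The direction of change followed the GC content of the transcript. Of 2522 genes with a GC content of at least 50%, 98.1% were higher in C1s-CM, and of 2585 genes below it, 6.00% were. Across genes, which are not independent replicates, Spearman's rho between the log2 fold change and GC content was 0.85, and with length -0.55. Each gene's log2 CPM was centred on its mean over the 6 libraries, which makes the mean slopes of the groups equal and opposite, so that only their difference carries information. The slope on GC content differed between the groups by 0.33 per 10 percentage points, with an SD between libraries of 0.0006 in C1s-CM and 0.014 in control CM (n = 3 each). With GC and length offsets, an alternative chosen after seeing the data, 1292 genes passed the threshold, 751 higher and 541 lower. Only 9 genes were then at least 2-fold higher and 2 at least 2-fold lower. Of the 1292 genes, 1270 were called in both analyses and 843 in the same direction in both. Values with offsets below use a representative transcript per gene. With the longest transcript 110 of the 114 reported genes with a GC value had the same direction, and 8 lay on the other side of the threshold.

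**Figure D2:**
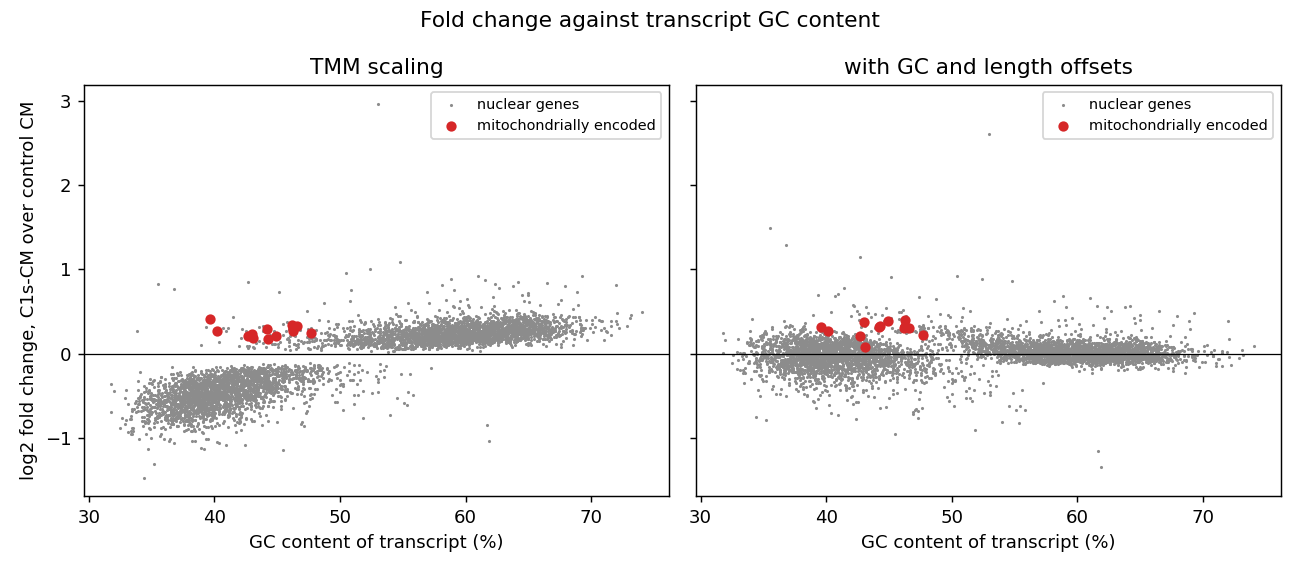
Log2 fold change of C1s-CM over control CM (vertical axes) against transcript GC content in percent (horizontal axes), each point a gene, with TMM scaling on the left and GC and length offsets on the right, and the 13 mitochondrially encoded genes as large points. The 5 genes at 0 in controls are left out, genes that did not pass the authors' threshold have no point, which empties the band around 0 on the left, and the median absolute log2 fold change is 0.31 on the left and 0.08 on the right.

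All 13 mitochondrially encoded respiratory chain genes rose, with a median log2 fold change of 0.27, among them MT-CO2 (0.34 ± 0.03, SE), MT-CO3 (0.32 ± 0.03), MT-ATP6 (0.29 ± 0.03) and MT-CYB (0.27 ± 0.03). Of 35 nuclear respiratory chain genes with a row (51 listed) 27 rose and 8 fell, and NDUFB7 (0.45), NDUFS8 (0.43), UQCRC1 (0.37) and COX5B (0.37) rose. Of 16 glycolysis genes with a row (22 listed) 15 rose and 1 fell. Those with the smallest p were the enzymes TPI1 (0.37), PFKL (0.37), PKM (0.35) and GAPDH (0.33), each with an SE of 0.03. With total counts as the only scaling 10 mitochondrial genes were called higher and 0 lower (median 0.14), 18 nuclear genes higher and 8 lower (0.14), and 9 glycolysis genes higher and 1 lower (0.11). Camera at the preset correlation called all 3 lists higher than the other genes of the table, with adjusted p of 0.000136 (mitochondrial), 0.000276 (nuclear) and 0.000276 (glycolysis), and gave adjusted p = 0.518 for each with an estimated correlation. The median GC content was 44.3% for the mitochondrial, 53.04% for the nuclear and 56.8% for the glycolysis transcripts, and the median log2 fold changes with offsets were 0.31, 0.06 and 0.11. Without offsets, 20.4% of all genes with a GC content of 43.7 to 49.3% were higher in C1s-CM. The share was 89.6% from 49.3 to 55.5% and 99.4% from 55.5 to 58.6%. The counts of nuclear and glycolysis genes that rose are therefore near or below what their GC content alone would give. After offsets 13 mitochondrial, 16 nuclear and 7 glycolysis genes were called higher, and with an estimated correlation camera gave adjusted p of 0.00899, 0.106 and 0.295. NDUFB7 (0.05) missed the threshold after offsets, and the other genes named here passed it.

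Of 31 ribosomal protein genes 29 rose and 2 fell; RPS9 (0.37) and RPL35 (0.31) rose and RPL7 (-0.37) fell, though processed pseudogenes make such counts uncertain. Of 14 serine, one-carbon and ATF4-linked genes 12 rose, including TRIB3, a stress-induced pseudokinase (0.36), the serine synthesis enzyme PHGDH (0.26) and the amino acid transporter subunits SLC7A5 (0.26) and SLC3A2 (0.25). Camera gave adjusted p of 5.59e-06 and 0.0228, and 0.574 and 0.518 with an estimated correlation. With total counts as the only scaling 19 ribosomal protein genes were higher and 3 lower (median 0.12), 9 serine, one-carbon and ATF4-linked genes were higher and 2 lower (0.11), and the latter list lost its call (adjusted p = 0.0657). The median GC contents were 52.2% and 58.1%, and the medians with offsets 0.07 and 0.08, with adjusted p of 0.195 and 0.295 at an estimated correlation. Without offsets, 89.6% of all genes with a GC content of 49.3 to 55.5% were higher, and 99.4% from 55.5 to 58.6%. The count of ribosomal protein genes that rose is near what their median GC content alone would give, and that of the other list is below it. After offsets 16 ribosomal protein genes were called higher and 5 lower, and 7 serine, one-carbon and ATF4-linked genes higher and 0 lower. With offsets RPS9 (0.07), RPL7 (-0.21) and TRIB3 (0.12) passed the threshold, PHGDH (0.06), SLC7A5 (0.04) and SLC3A2 (0.04) missed it, and RPL35 turned to -0.03. With the longest transcript RPL7 (-0.07) missed it. These 5 lists were the only ones of 25 called at the preset correlation, none was called with an estimated correlation, and fry called 21. Splits of the libraries that mixed the groups also gave up to 5 lists at the preset correlation, so the number of lists does not set the groups apart.

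**Figure D3:**
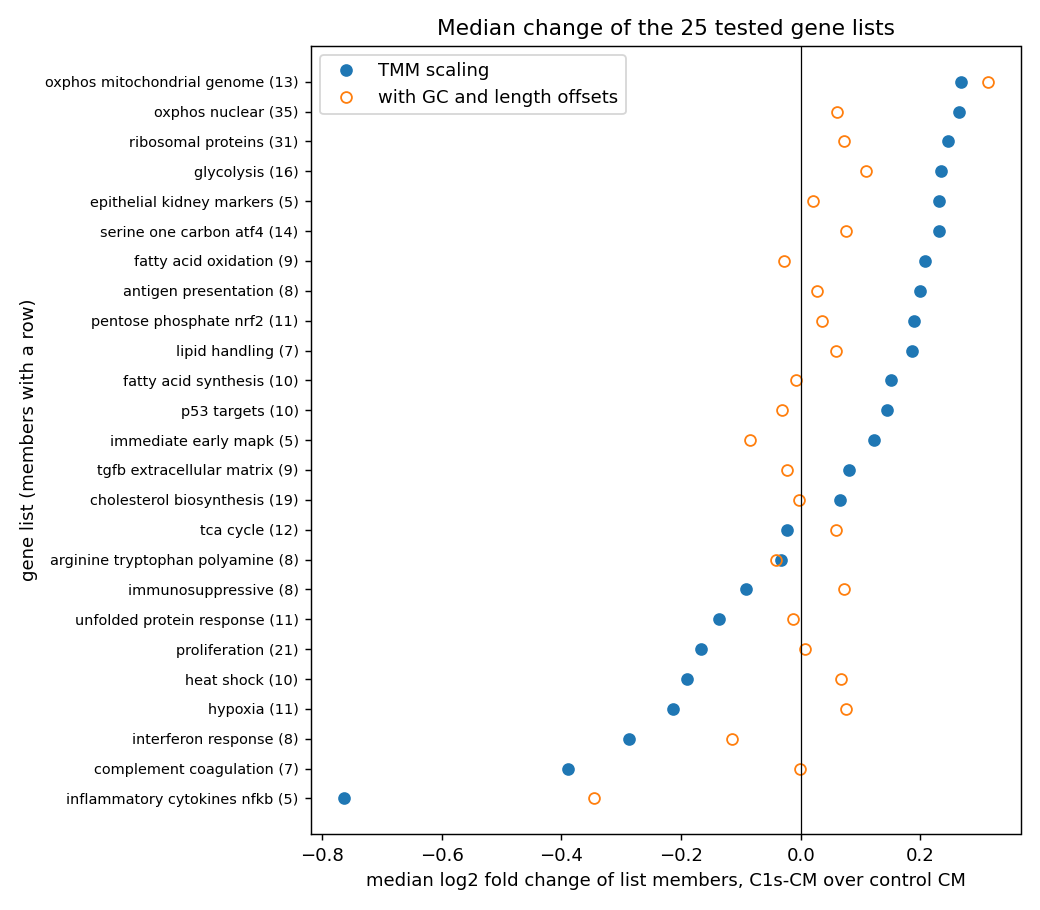
Median log2 fold change of the members of each of the 25 tested gene lists (horizontal axis; lists on the vertical axis with the number of members in the table), with TMM scaling (filled) and with GC and length offsets (open). The mitochondrially encoded genes have medians of 0.27 and 0.31, and the inflammatory list has -0.76 and -0.35.

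Of 5 NF-kB and cytokine genes with a row, 4 fell, the chemokine CXCL8 (-0.88 ± 0.10), the cytokine IL6 (-0.76 ± 0.17), BIRC3 (-1.14 ± 0.20) and the superoxide dismutase SOD2 (-0.40 ± 0.05). The list had a median GC content of 41.7%, and camera gave adjusted p = 0.354. With offsets CXCL8 (-0.35) and IL6 (-0.58) still passed the threshold, and SOD2 (0.03) and BIRC3 did not. The immunosuppressive list was divided, with 4 of 8 genes higher and 4 lower. CD163, TGFB1 (0.52 ± 0.03) and LGALS1 (0.40 ± 0.03) rose and TGFB2 (-0.41 ± 0.05) fell, with camera adjusted p = 0.216. TGFB1 was 0.27 and LGALS1 0.08 higher with offsets, both past the threshold, while TGFB2 turned to 0.0997 and missed it, and the median of the list was -0.09 before offsets and 0.07 after. With offsets camera called this list at the preset correlation (adjusted p = 0.00339), and gave adjusted p = 0.195 with an estimated correlation. After offsets 3 of the 8 genes were called higher, CD163 among them, and 2 lower. With offsets the list was not tested without CD163, so the call does not show a rise of the list as a whole. CD163 is the member at 0 in controls, and the mean of the list, 1.24, is above 0 because of its fitted value, which is no bound. The interferon list had 3 higher and 5 lower, with ISG15 (0.34) higher and IFIH1 (-0.61) and GBP1 (-0.49) lower. Antigen presentation genes had 6 higher and 1 lower of 8, with PSMB8 (0.23) and HLA-DMA (0.26) higher and B2M (-0.33) lower. Complement and coagulation genes had 2 higher and 5 lower, and CD46 (-0.45), F2R (-0.39), CD59 (-0.22) and TFPI (-0.58) fell. With total counts as the only scaling HLA-DMA missed the threshold. With offsets IFIH1 (-0.28) and CD59 (-0.23) still passed the threshold. ISG15 (-0.03), B2M (0.03) and CD46 (0.01) turned and missed it, and GBP1 (-0.17), PSMB8 (0.03), HLA-DMA (0.10), F2R (-0.10) and TFPI (-0.0008) missed it too. With the longest transcript CD59 turned to 0.05 and missed the threshold, and B2M was -0.0088.

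Other metabolic lists were mixed, and camera called none of them. In the order below they held 24, 19, 24, 16, 23, 22 and 22 genes, and the counts are of members with a row. Of 12 citric acid cycle genes 6 rose and 6 fell, with IDH3G (0.32) and IDH3B (0.23) higher and MDH1 (-0.25) and DLD (-0.39) lower. Of 11 pentose phosphate and NRF2 genes 9 rose, including FTL (0.30) and TKT (0.19), and TXNRD1 (-0.30) fell. Of 19 cholesterol synthesis genes 11 rose and 8 fell, with MVD (0.29) higher and STARD4 (-0.64), HMGCS1 (-0.38) and MSMO1 (-0.35) lower. Of 10 fatty acid synthesis genes 6 rose and 4 fell, FASN (0.27) among the first and ACSL4 (-0.62), ACSL3 (-0.38) and ELOVL5 (-0.30) among the second. Of 9 fatty acid oxidation genes 7 rose, including ACADS (0.39), ECI1 (0.33), ECHS1 (0.21) and ACADVL (0.18). After offsets 1 fatty acid oxidation gene was called higher and 0 lower, and the median of the list went from 0.21 to -0.03. The median GC content was 56.3% for the pentose phosphate and NRF2 genes and 60.1% for the fatty acid oxidation genes. Without offsets, 99.4% of all genes with a GC content of 55.5 to 58.6% were higher, and 100% from 58.6 to 61.1%. The counts of these 2 lists that rose are below those shares. Of 7 lipid handling genes 5 rose, including APOC1 (0.59), PLIN3 (0.27) and PNPLA2 (0.19), and MYLIP (-0.34) fell. Of 8 arginine, tryptophan and polyamine genes 4 rose, including ASL (0.38), SRM (0.28) and OAZ1 (0.21), and 4 fell, including the aryl hydrocarbon receptor AHR (-0.63). ACADVL and PNPLA2 missed the threshold with total counts as the only scaling. With offsets only MDH1 (-0.13), APOC1 (0.34), MYLIP (-0.45) and ASL (0.15) of the genes named in these lists kept direction and threshold. MSMO1 (0.08), ACSL3 (0.15), ELOVL5 (0.09) and PNPLA2 (-0.09) passed the threshold in the opposite direction. DLD (0.06), TXNRD1 (0.03), TKT (-0.0009), HMGCS1 (0.04), MVD (-0.0031), ECHS1 (-0.05), ACADVL (-0.03) and SRM (-0.03) turned and missed it. IDH3G (0.06), IDH3B (0.06), FTL (0.06), STARD4 (-0.01), ACSL4 (-0.07), ACADS (0.11), ECI1 (0.06), PLIN3 (0.06), OAZ1 (0.03), AHR (-0.18) and FASN, whose adjusted p was 0.999, missed it without turning. With the longest transcript MSMO1 (0.06), ELOVL5 (0.04), MYLIP (-0.17) and ASL (0.15) missed the threshold, and TXNRD1 was -0.03. For cholesterol and fatty acid synthesis the median was above 0 (0.07 and 0.15) while the mean (-0.06 and -0.09) and camera's direction were below it.

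Stress, growth and matrix lists were also not called by camera. In the order below they held 20, 21, 14, 18, 32, 25 and 26 genes, and the counts are of members with a row. Of 11 hypoxia genes 5 rose and 6 fell, with DDIT4 (0.21) higher and LOX (-0.48), BNIP3L (-0.29) and P4HA1 (-0.26) lower. Of 11 unfolded protein response genes 3 rose and 6 fell, and HSP90B1 (-0.46), SEL1L (-0.41), CANX (-0.18) and DNAJC3 (-0.58) fell. Of 10 heat shock genes 4 rose and 6 fell, with HSPB1 (0.25) higher and HSP90AA1 (-0.50), HSPA8 (-0.27) and HSPA4 (-0.26) lower. Of 10 p53 targets 7 rose, including FDXR (0.35), BAX (0.21) and CDKN1A (0.16), and MDM2 (-0.62) was among 3 that fell. After offsets 0 p53 targets were called higher and 2 lower. Their median GC content was 57.0%, and without offsets 99.4% of all genes from 55.5 to 58.6% were higher. Of 21 proliferation genes 10 rose and 11 fell, and TOP2A (-0.63), KIF11 (-0.65), CDK1 (-0.43) and CENPF (-0.59) fell. Of 5 immediate-early genes 3 rose, including FOSL1 (0.23) and ETV4 (0.22), and SPRED1 (-0.62) and PHLDA1 (-0.42) fell. Of 9 TGF-beta and matrix genes 5 rose and 3 fell, with FN1 (0.36) and TAGLN (0.31) higher and SKIL (-0.96) and LOX lower. CDKN1A and ETV4 missed the threshold with total counts as the only scaling. With offsets HSP90B1 (-0.13), HSP90AA1 (-0.17), HSPA8 (-0.13), MDM2 (-0.29), TOP2A (-0.13), KIF11 (-0.14), SKIL (-0.24), FN1 (0.45) and TAGLN (0.13) kept direction and threshold. BNIP3L (0.17), P4HA1 (0.11), SEL1L (0.11), CANX (0.22), HSPB1 (-0.09), HSPA4 (0.12) and BAX (-0.11) passed the threshold in the opposite direction. DDIT4 (-0.0072), CDKN1A (-0.04), CDK1 (0.05), FOSL1 (-0.01) and ETV4 (-0.0097) turned and missed it, and LOX (-0.0061), DNAJC3 (-0.10), FDXR (0.07), CENPF (-0.12), SPRED1 (-0.08) and PHLDA1 (-0.09) missed it without turning. With the longest transcript BAX (-0.06) missed the threshold, and CDK1 was -0.0095.

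The microglia and macrophage list had under 5 members with a row and was not tested. Of the astrocyte and glioma markers GJA1 (-0.32) was the only 1 of 15 with a row. Fibroblast and pericyte markers THY1 (0.15), S100A4 (0.34) and PDGFRB (0.12) were higher, and 4 of 5 epithelial markers with a row were higher, among them KRT18 (0.31), KRT8 (0.23) and PAX8 (0.11), while CLDN1 (-0.35) was lower. With total counts as the only scaling PDGFRB and PAX8 turned to -0.009 and -0.014, and THY1, KRT8 and the histone H2BC12 missed the threshold. The replication histones H1-2 (0.19) and H2BC12 (0.15) were higher, and such transcripts are captured by poly(A) selection only in part. With offsets H1-2 (-0.10) and H2BC12 (-0.24) passed the threshold in the opposite direction, and none of the marker genes named here passed it, except KRT18 (0.09) with the longest transcript. The endothelial and the neuron and oligodendrocyte lists had no member with a row. Adjusted over the list alone, as many members passed the threshold in each list as over all genes tested. All 115 genes reported under the rule passed the threshold in edgeR, with a largest adjusted p of 0.00257 for PDGFRB. Both results were largely set in advance, since the table had been selected by a test on the same counts.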

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

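The GC and length offsets, the adjustment over all genes implied by the authors' adjusted p, the scaling to the authors' median and the run without the 5 genes at 0 in controls were chosen after the data had been seen. The 115 genes reported under the rule and 11 others kept direction and threshold under RLE size factors, no filter, DESeq2, limma-voom, the adjustment over all genes implied, the authors' median and each left-out library, and the filter of 50 counts kept 118 of these 126 and removed the rest. Same-numbered libraries did not deviate together (correlations -0.128, -0.087 and -0.003), so the numbers were not used to pair them. Such correlations cannot exclude that same-numbered libraries were cultured or prepared together. With a replicate block 5054 genes were called, 2573 higher and 2481 lower. Total counts only gave 1336 genes higher, 54 at least 2-fold lower and camera adjusted p = 0.0657 for the serine and one-carbon list. This scaling took 9 of the 126 genes below the threshold (ACADVL, PNPLA2, HLA-DMA, HLA-DPB1, CDKN1A, ETV4, THY1, KRT8 and H2BC12), and turned PDGFRB (-0.009) and PAX8 (-0.0143). The cause was not tested. Those totals cover called genes alone and are not depth. The median log2 fold change was -0.05 with total counts, 0.08 with TMM and 0.12 when scaled to the authors' median, so the authors' scaling lay on the other side of TMM. The filter of 50 counts gave 10 genes at least 2-fold lower, since fewer genes were tested. Leaving out 1 library gave 7 to 11 genes at least 2-fold higher, with 11 without C1s-CM replicate 1 and 11 without control CM replicate 2. An estimated correlation called 0 lists (adjusted p 0.574 for ribosomal proteins and 0.518 for the mitochondrial, nuclear respiratory chain, glycolysis and serine lists, whereas camera at the preset correlation called 5), and fry, which does not compare a list with other genes, called 21. GC and length offsets gave 1292 genes, 751 higher and 541 lower, with 2 at least 2-fold lower, and the longest transcript gave 1244, 739 higher and 505 lower, with 2 at least 2-fold lower. The offsets remove a trend by construction. They turned DLD (0.0616), TXNRD1 (0.0293), TKT (-0.0009), HMGCS1 (0.0356), MSMO1 (0.082), MVD (-0.0031), ACSL3 (0.1523), ELOVL5 (0.0894), ECHS1 (-0.0454), ACADVL (-0.0273), PNPLA2 (-0.0889), SRM (-0.0298), TGFB2 (0.0997), SOD2 (0.0336), ISG15 (-0.0274), B2M (0.03), CD46 (0.0143), BNIP3L (0.1708), P4HA1 (0.1113), DDIT4 (-0.0072), SEL1L (0.1148), CANX (0.2228), HSPB1 (-0.0904), HSPA4 (0.119), BAX (-0.1099), CDKN1A (-0.0405), CDK1 (0.0534), FOSL1 (-0.0146), ETV4 (-0.0097), GJA1 (0.0772), THY1 (-0.0227), PDGFRB (-0.0363), CLDN1 (0.0324), PAX8 (-0.0482), RPL35 (-0.0278), H1-2 (-0.0996), H2BC12 (-0.236) and SRGN (0.0666), and took 32 others below the threshold. The C1S level has no alternative, since C1S has no row. Counts near the floor limit the folds of the 5 genes at 0 in controls to lower bounds.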

Other observations

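The families below were chosen after their values were seen, with no test of enrichment. Of 107 zinc finger (ZNF) genes with a row 33 rose and 74 fell, with a median log2 fold change of -0.50 and a median GC content of 42.2%. Of 19 centrosome and cilium (CEP) genes 2 rose and 17 fell. Of 38 mitochondrial ribosome genes 31 rose and 7 fell, with a median of 0.23 and a median GC content of 54.1%. The medians kept their signs with RLE size factors, total counts only and the authors' median, but with total counts only 14 ZNF genes were higher and 74 lower, 0 CEP genes higher and 17 lower, and 21 mitochondrial ribosome genes higher and 7 lower (median 0.10). With offsets 2 ZNF genes were higher and 8 lower (median -0.09), 0 CEP genes higher and 4 lower (-0.13), and 14 mitochondrial ribosome genes higher and 3 lower (0.05).

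Some changes stayed large with offsets, again chosen after their values were seen. CTSC, the lysosomal protease cathepsin C, rose by 0.73 ± 0.04 on the log2 scale (SE) and by 0.91 with offsets. SLC4A7, a sodium bicarbonate cotransporter, rose by 0.83 ± 0.08 and by 1.48 with offsets, and TGFBR2, a TGF-beta receptor, by 0.50 ± 0.09 and by 0.68. RBMS3 was -0.81 before and -0.70 after offsets, PTAR1 -0.80 and -0.64, and SERPINA1, the antitrypsin gene, -0.73 and -0.81.

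The tests below were chosen after the results had been seen, except those on splits of the libraries. The direction of the called genes followed GC content, and the slopes of the groups on GC content, of values centred per gene, lay 34.58 pooled SDs apart. A GC-dependent bias of library preparation or sequencing that differed between the groups may account for it, and so may a response of the cells whose genes differ in GC content. No label gives a library batch, so these cannot be told apart here. The smallest exact permutation p of 3 slopes against 3 is 0.1, and the table holds called genes alone.

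The rises of the mitochondrially encoded, nuclear respiratory chain and glycolysis lists were weighed apart. For mitochondrially encoded genes the values argue against the GC trend as the whole cause. Nuclear genes in their GC range were higher in 5.16% of 1395 cases, and 13 of the 13 stayed past the threshold after offsets. Those nuclear genes were matched on GC content alone, not on length or abundance. Of the 1277 shortest genes 83.7% were higher, with a median GC content of 57.8%. The offsets took in length but not abundance, which also went with the fold change (Spearman's rho 0.45). For glycolysis and the nuclear respiratory chain the GC trend stays open as the whole cause. With offsets their median log2 fold changes fell from 0.23 to 0.11 and from 0.26 to 0.06, while camera's adjusted p at the preset correlation stayed below the threshold. The largest adjusted p after offsets, that of camera with an estimated correlation, was 0.2948 and 0.1062. It had been 0.518 for both before offsets, so that setting cannot decide. A difference in cell state or RNA quality between the groups could also raise mitochondrial transcripts and was not tested, and the treatment itself stays open.

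The 5 genes at 0 in controls stood apart from the table. After offsets, the smallest lower bound of their log2 fold changes, against 3 counts in each control library, was 6.3878. The largest value of all other genes was 2.60. The offsets remove a trend far smaller than such bounds, so this comparison was largely set in advance and decides nothing. Before offsets the lower bounds ran from 6.11 (IGF1) to 7.15 (CXCR4). In groups of genes ordered by GC content, the median log2 fold changes ran from -0.59 to 0.30. A GC trend of that size falls far short of the bounds, which argues against it as the cause for these 5 genes. Their authors' fold changes departed from a DESeq2 refit of the counts by at most 0.0003086 beyond the median departure, below the 0.00194 of other genes. The counts shown are therefore those behind the authors' values. The refit cannot show an error that entered the counts before the authors' fit, and such an error was not tested. Myeloid cells or their RNA in the C1s-CM libraries could bring such transcripts: of 36 abundant myeloid transcripts, listed after many values had been seen, 7 have a row, 5 higher (CD302 0.77, CTSC 0.73, APOC1 0.59, HLA-DMA 0.26 and HLA-DPB1 0.25, the last 2 not past the threshold with total counts only) and 2 lower (SRGN -0.28 and ENTPD1 -0.84). Of the 2 with under 100 counts in controls 1 did not rise. Listed transcripts without a row did not pass the authors' threshold or were not among the genes adjusted over, and they have no values here. A rise like that of the 5 genes at 0 in controls would have been expected to give a row. The listed transcripts that rose go with admixture, and those that fell or have no row go against it. Admixture and induction by the treatment therefore cannot be told apart.

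The real split of the 6 libraries gave 5086 genes and the highest of the other 9 splits 1. The genes of the table had been selected by the authors' test of this same split, so this contrast was largely set in advance. It carries no evidence that the groups differ. With 10 splits the share also cannot fall under 0.05 (1 of 10 gave as many). For gene lists 5 of the 10 splits gave at least 5 lists, and the highest of the others also gave 5.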
